A study of Mus musculus with 19 samples.

How the data were processed

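Total RNA from frozen sections of the left ventricle was amplified, coupled to Cy5 and hybridized to 19 Agilent mouse arrays, of which 6 belong to sham, 7 to HF_shDB and 6 to HF_DB mice. The groups, the weeks of surgery (0 and 2), the week of harvest (4) and the age label of 11 weeks were taken from the labels. The scanner files hold spot intensities that, per the file headers, Agilent Feature Extraction 11.5.1.1 had background-subtracted and detrended in the red channel without normalization between arrays. They also hold other values, namely spot flags, which were used as deposited. The authors also deposited a table of log2 values with 1 value per probe, which is quantile normalized between arrays: the sorted columns differ by at most 0.0038. That table served as an alternative. Per the file headers the array design was annotated on mm9. No coordinates were used, and a RefSeq table served only to bring 743 of 28663 matched probes to current symbols.

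From the scanner files, control spots and spots marked as outliers were left out, processed signals were taken to log2, and the 75th percentile of each array over non-control probes was subtracted. A floor planned for signals at or below 0 was not needed, since every processed signal lay above 0. Spots of a probe were averaged, which gave 39429 probes, and 419 of 749151 probe values were missing after outlier spots were left out. A probe was kept where it lay well above background on at least 6 of the 19 arrays, and each gene was represented by its probe with the highest mean signal, which left 18882 genes. The depth of an array is its signal over background, given in the report. All 19 arrays entered a single fit in limma 3.58.1 (R 4.3.3, statmod 1.5.0, data.table at version 1.17.8) with a coefficient per group, empirical Bayes moderation and Benjamini-Hochberg adjustment over all genes kept, and an adjusted p under 0.05 was called. The 3 comparisons were HF_shDB with sham, HF_DB with HF_shDB and HF_DB with sham. All tests were two-sided. Figures were drawn with matplotlib 3.10.9.

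Before the data were examined, 34 gene lists were written for cardiac stress, contraction, ion channels, metabolism, matrix, inflammation, protein quality control, the cell cycle, the clock and the cell types the sections could hold. They were tested with camera at a preset correlation of 0.01, adjusted over 102 tests. Camera was repeated with the correlation estimated per list, and fry was run as well. Of 51 camera calls, 0 held with an estimated correlation and 16 held with fry. Camera compares a list with all other genes, and fry tests whether the genes of a list move on balance 1 way. After the data had been examined, an exact permutation test of the list mean per array was added, adjusted over the same 102 tests, and it called 14.

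Genes were named by a rule fixed before the data were examined. In each comparison it takes the 6 highest and 6 lowest log2 differences among genes past the threshold that have an established symbol and all arrays of 1 group beyond the mean of the other. It adds a fixed set (Nppa, Nppb, Myh7, Myh6, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Timp1, Ccn2, Lox and Cpt1b). From each list that is called, or has enough members past the threshold, it adds up to 3 members with the lowest adjusted p and up to 1 that moved the other way. Other genes in the text are marked as named after their values were seen. A gene whose reference group lay above background on 0 arrays is given as a lower bound of its fold.

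Comparisons that share a control group were set beside 20 simulations of unchanged groups and beside splits of the shared arrays. The share of the difference left after debanding used 50 random splits of the sham and HF_shDB arrays, in which genes past the threshold (or the 500 with the largest statistic where fewer than 100 passed) were chosen on one part and measured on the other. Counts were compared with 100 splits of the arrays into groups of the same sizes, the real split included. The pipeline was tested on simulated data with 200 changed genes. It recovered 88.1%, 85.1% and 91.0% of the genes changed by 1 log2 unit in the 3 comparisons and 31.3%, 38.8% and 23.9% of those changed by 0.5. Of its calls, 5.81%, 4.52% and 8.39% were unchanged genes. The share left was simulated apart, with 1000 genes changed by 1.5 log2 units and noise independent between genes. Shares of 0.5 and 1 were returned as 0.503 and 1.01. In the real arrays a median of 3.5 genes passed in the choosing part. The simulation thus does not show how exact the share is there.

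Alternatives planned before the data were examined changed the normalization (quantile), the background correction (normexp with an offset of 50), the source (the table of the authors), the filter, the choice of probe, the model and the thresholds, and left out each array in turn. Alternatives added after the data had been examined were slide as a fixed block, the marker list means of adipocytes and atrial myocytes as covariates (together and singly), that of epicardial cells as a covariate, and fits without the 6 arrays more than 2 log2 units above the mean in adipocyte markers or the 7 above it in atrial markers. High in adipocyte markers were sham replicate 1, HF_shDB replicates 4 and 6 and HF_DB replicates 1, 2 and 3. High in atrial markers were sham replicate 1, HF_shDB replicates 1, 4 and 6 and HF_DB replicates 2, 3 and 6. Fits without them rest on few arrays per group. A block for scan date was planned and not fitted, since all arrays were scanned on 1 day. No array or group was left out of the comparisons reported.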

Results

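Gene expression was measured in the left ventricle of 19 female C57BL/6 mice with 1-colour oligonucleotide microarrays, 1 array per mouse. In 6 mice both operations were sham (sham). In 7 mice the transverse aorta was constricted and a small apical infarct was made at week 0, followed by a sham operation at week 2, so the constriction stayed in place (HF_shDB). The remaining 6 mice had the same first operation, and the band around the aorta was removed at week 2 (HF_DB). All ventricles were taken at week 4. The median processed signal of the arrays ranged from 206 to 423, their 75th percentile from 1408 to 2708, and 56.2% to 65.1% of the spots lay well above background. The mean percentage well above background was 59.0 ± 2.69 in sham (SD, n = 6), 59.4 ± 1.45 in HF_shDB (n = 7) and 60.9 ± 2.67 in HF_DB (n = 6). The arrays lay on 5 slides that mixed the groups, except that 1 slide held no HF_DB array and 1 held no sham array. Levels are log2 signals minus the 75th percentile of the array, differences are given with the standard error of the fit, and the number of arrays limits their precision.

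The comparison of HF_shDB with sham asks which genes differ after 4 weeks of constriction with infarction. Natriuretic peptide genes, fetal and skeletal muscle isoforms and 7 of 22 collagens and structural matrix genes were higher in HF_shDB, while the ion channel genes Kcnv2 and Kcnj2 and the clock output genes Hlf and Tef were lower. Acta1, which encodes skeletal muscle actin, was 8.88-fold higher (log2 difference 3.15 ± 0.41, 7 against 6 arrays). Nppb and Nppa, which encode the natriuretic peptides, were 3.48-fold and 2.69-fold higher, and the matrix genes Timp1 (a metalloproteinase inhibitor) and Postn (periostin) were 5.30-fold and 5.15-fold higher. Of 18882 genes, 376 passed an adjusted p of 0.05 in limma, 193 higher and 183 lower, and 101 of them differed by at least 1 log2 unit, 78 higher and 23 lower.

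The largest rises among the genes chosen by rule were in Saa3 (an acute phase protein; log2 difference 3.63 ± 0.87), Myh7 (the beta myosin heavy chain; 3.23 ± 0.79), Acta1, Dio2 (a deiodinase that activates thyroid hormone; 2.91 ± 0.44), Cilp (a matrix protein; 2.85 ± 0.62) and Serpina3n (a protease inhibitor; 2.60 ± 0.39). The largest falls were in Ano10 (-1.67 ± 0.28), Clec18a (-1.64 ± 0.22), the orphan receptor gene Gpr22 (-1.42 ± 0.28), Klhl33 (-1.39 ± 0.25), the potassium channel subunit gene Kcnv2 (-1.35 ± 0.23) and Cth, which encodes cystathionine gamma-lyase (-1.18 ± 0.25). A second kept probe of Ano10 had the opposite sign (0.37, adjusted p = 0.154). Clec18a was well above background on 2 of the 7 HF_shDB arrays and Kcnv2 on 4 of them.

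The cardiac stress programme rose in HF_shDB, with 9 of its 15 genes past the threshold, all higher (12 when adjusted over the list alone). Besides Acta1, Myh7, Nppb and Nppa, these included the stretch-responsive gene Ankrd1 (1.65 ± 0.25). The mean of the list was 2.99 ± 0.44 (SD, n = 7) in HF_shDB and 1.58 ± 0.23 (n = 6) in sham, and higher on each of the 4 slides that held both groups, by 1.00 to 1.91. Camera gave an adjusted p of 2.04e-18, and the adjusted exact permutation p of the list means was 0.0297 (adjusted p = 0.164 with an estimated correlation). The adult contractile and calcium handling genes were not called (adjusted p = 0.486), with 0 of 20 members past the threshold (1 lower when adjusted over the list alone). The log2 difference was -0.11 ± 0.17 for Myh6 (the adult alpha myosin heavy chain) and -0.31 ± 0.15 for Atp2a2 (the calcium pump of the sarcoplasmic reticulum).

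The matrix lists rose together in HF_shDB. Collagens and structural matrix had 7 of 22 genes higher (20 when adjusted over the list alone), among them the fibrillin gene Fbn1 (1.65 ± 0.30) and the proteoglycan gene Bgn (1.21 ± 0.24). Matricellular proteins had 3 of 13 higher (9 over the list alone), namely Postn (2.36 ± 0.44), Ccn2 (1.70 ± 0.35) and Ccn5 (2.54 ± 0.64). Matrix processing enzymes and inhibitors had 6 of 23 higher (11 over the list alone), including Timp1 (2.41 ± 0.40), the stromelysin gene Mmp3 (1.81 ± 0.38) and the crosslinking enzyme gene Loxl1 (1.44 ± 0.29). Transforming growth factor beta signalling and myofibroblast genes had 5 of 19 higher (12 over the list alone), including Fstl3 (1.39 ± 0.21), Meox1 (1.53 ± 0.31) and Fstl1 (1.06 ± 0.25). The adjusted exact permutation p of the list means was 0.0297, 0.0297, 0.0297 and 0.0401 in that order, and the list means were higher on all 4 slides, by 0.48 to 2.29 for the collagens. Camera gave adjusted p values from 1.72e-20 to 8.43e-10 (adjusted p = 0.253 with an estimated correlation for each of these lists). The differences of Col1a1 (1.20 ± 0.39, adjusted p = 0.111), Col3a1 (1.35 ± 0.36, adjusted p = 0.0583) and Lox (1.95 ± 0.53, adjusted p = 0.0597) did not pass the threshold.

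Macrophage and monocyte markers were higher as a list in HF_shDB, with 0 of 18 members past the threshold on their own (8 higher when adjusted over the list alone). Their list mean differed by 0.44, with an adjusted exact permutation p of 0.0473 and a camera adjusted p of 1.53e-08 (adjusted p = 0.253 with an estimated correlation). Neutrophil markers differed by 0.76, with 1 of 7 past the threshold (over the list alone, 4 higher and 1 lower), Lcn2 (lipocalin; 1.14 ± 0.28). The adjusted p of this list was 0.00248 by camera, 0.253 with an estimated correlation and 0.0401 by exact permutation. Fibroblast markers differed by 0.26 with 1 of 10 past the threshold (over the list alone, 3 higher and 1 lower), Pi16 (1.03 ± 0.19), and passed camera (adjusted p = 0.00202, and 0.447 with an estimated correlation) but not the exact permutation (adjusted p = 0.215). Without HF_shDB replicate 4 the difference was 0.15 (camera adjusted p = 0.0493).

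Cardiac ion channels fell in HF_shDB. Of the 16 genes measured, 2 were lower (7 over the list alone), Kcnv2 and the inward rectifier gene Kcnj2 (-0.87 ± 0.21). Their list mean differed by -0.34, with an adjusted p of 0.00178 by camera, 0.409 with an estimated correlation and 0.0297 by exact permutation. Cytoskeleton and Z-disc remodelling genes were higher by 0.24 as a list with 0 of 16 past the threshold (0 over the list alone), with an adjusted p of 0.000723 by camera, 0.355 with an estimated correlation and 0.0297 by exact permutation. The camera call of this list was lost with normexp background correction (adjusted p = 0.0905). Energy metabolism lists passed camera at smaller shifts. The list mean of fatty acid uptake and oxidation differed by -0.27 (adjusted p = 2.70e-06, and 0.495 with an estimated correlation), with 1 of 25 members lower (1 over the list alone), Acaa2, a thiolase (-0.56 ± 0.13). The tricarboxylic acid cycle differed by -0.20 (adjusted p = 0.00107, and 0.575 with an estimated correlation) and oxidative phosphorylation by -0.18 (adjusted p = 0.000901, and 0.655 with an estimated correlation), with 0 members past the threshold in either, also over each list alone. None of the 3 passed the exact permutation (adjusted p = 0.168, 0.230 and 0.298). Cpt1b differed by -0.19 ± 0.16. Egr2, an immediate early gene, was at least 1.47-fold higher, the bound from a sham group in which 0 of 6 arrays lay above background. It was the member past the threshold of the 15 immediate early genes (3 over the list alone), whose list mean differed by 0.31 (adjusted p = 0.0194 by camera, 0.524 with an estimated correlation and 0.0764 by exact permutation). The camera call was lost without sham replicate 1 (0.141) or HF_shDB replicate 3 (0.0791), with normexp (0.0579) and without the arrays high in adipocyte (0.0606) or atrial markers (0.1802).

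Circadian clock genes moved in opposite directions in HF_shDB, and the list as a whole was not called (camera adjusted p = 0.358). Of 14 measured, 2 were higher and 4 lower (4 and 6 over the list alone). Arntl, the activator of the clock, was higher by 1.82 ± 0.27, and the output regulators Hlf (-1.08 ± 0.15) and Tef (-0.84 ± 0.14) were lower. The others, named after their values were seen, were Nr1d1 (0.80 ± 0.16), Dbp (-0.66 ± 0.13) and Cry2 (-0.68 ± 0.17).

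Adipocyte markers and atrial myocyte markers varied widely between arrays in every group. The mean of the adipocyte list was 0.60 ± 2.81 (SD, n = 7) in HF_shDB and -0.89 ± 3.16 (n = 6) in sham, and that of the atrial list 2.53 ± 2.19 and 0.63 ± 2.56. Camera called both higher in HF_shDB (adjusted p = 0.0415 and 0.0410, and 0.695 and 0.589 with an estimated correlation), and the exact permutation called neither (adjusted p = 0.573 and 0.350). The camera call of the adipocyte list was lost without sham replicate 4, 5 or 6, HF_shDB replicate 1, 2, 4 or 6 or HF_DB replicate 1, and its difference of 1.49 became 2.53 without sham replicate 1, 0.87 and 0.86 without sham replicates 5 and 6 and 0.91 without HF_shDB replicate 4. That of the atrial list was lost without sham replicate 2, 5 or 6 or HF_shDB replicate 1, 2, 4 or 6. Both lists were higher on 3 of the 4 slides with both groups and lower on 1, and oxidative phosphorylation was lower on 3 of the 4. Of the 16 camera calls in HF_shDB against sham, 13 held without each array in turn and 12 in every other setting run with camera at the preset correlation. With both list means as covariates 766 genes passed, and 34 of the 34 named genes past the threshold kept their call. The count was 33 with normexp background correction, under which 14 of the 34 kept their call, 598 with slide as a fixed block, under which Myh7 (adjusted p = 0.0595) and Lcn2 (adjusted p = 0.0522) lost their calls, and 88 to 635 without any 1 array. Of the 34 named genes 18 kept their call without each array in turn, and Saa3, Myh7, Ccn5, Kcnj2, Acaa2, Fstl1, Lcn2 and Egr2 were among those that did not.

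**Figure D1:**
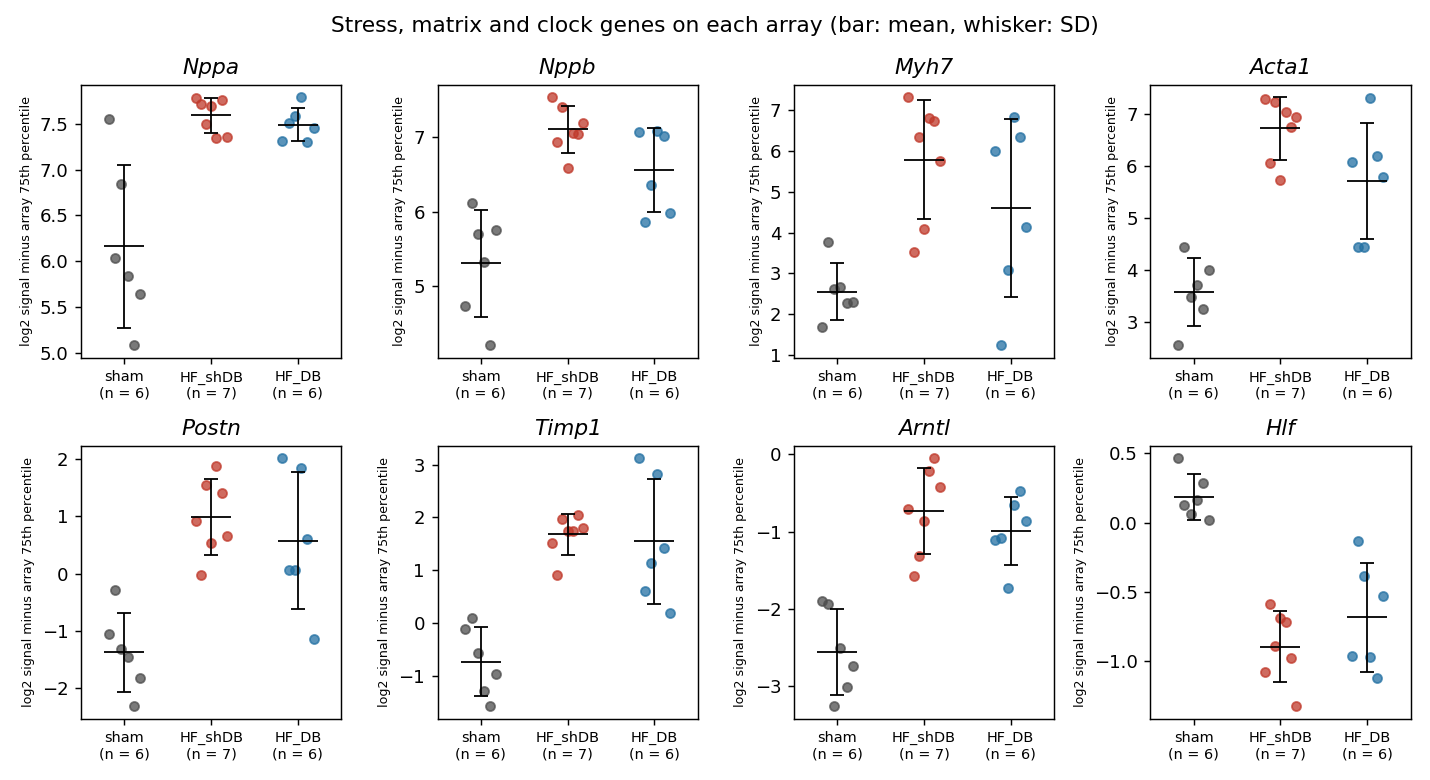
Levels of stress, matrix and clock genes on each array (log2 signal minus the 75th percentile of the array; points are arrays, bars are means and whiskers SDs; sham n = 6, HF_shDB n = 7, HF_DB n = 6). Acta1 was 3.56 ± 0.65 in sham and 6.71 ± 0.60 in HF_shDB, and the HF_DB arrays spread more widely (5.70 ± 1.11).

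The comparison of HF_DB with HF_shDB asks which genes differ when the band is removed at week 2. The stress genes stood lower in HF_DB by point estimate, and none passed the threshold. Acta1 differed by -1.01 ± 0.41 (6 against 7 arrays, 2.02-fold lower), Myh7 by -1.19 ± 0.79, Nppb by -0.54 ± 0.28 and Nppa by -0.10 ± 0.27. The matrix genes differed by 0.26 ± 0.39 (Col1a1), 0.16 ± 0.36 (Col3a1), -0.41 ± 0.44 (Postn), -0.12 ± 0.40 (Timp1), -0.08 ± 0.35 (Ccn2) and less than 0.01 for Lox (SE 0.53). Myh6 (-0.08 ± 0.17), Atp2a2 (0.03 ± 0.15) and Cpt1b (-0.12 ± 0.16) differed by less than their standard errors.

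Limma called 0 of 18882 genes in this comparison. The lowest adjusted p was 0.673, and 1389 genes had an unadjusted p under 0.05, where 944 were expected by chance. In simulated data with these group sizes, 85.1% of genes that differed by 1 log2 unit and 38.8% of those that differed by 0.5 were recovered, so smaller differences were mostly not detectable with these arrays. The simulation changed genes picked at random, with noise independent between genes. Acta1 and Myh7 had standard errors well above the median of 0.141 over all genes, so these rates do not apply to them. The 7 arrays high in atrial markers include HF_DB replicates 2, 3 and 6 and HF_shDB replicates 1, 4 and 6. Without them few arrays per group were left, and 6 genes passed, all higher in HF_DB. Named after their values were seen, these were Hps1 (1.05), 4933406B15Rik (0.94), LOC552909 (0.89) and the transcripts ENSMUST00000103418 (3.34), ENSMUST00000103335 (3.73) and ENSMUST00000103269 (0.90).

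Camera called 16 lists in HF_DB against HF_shDB, and the exact permutation of list means called 0. Of the 16 calls, 10 held without each array in turn and 2, lymphocyte markers and epicardial and mesothelial markers, in every other setting run with camera at the preset correlation. Neither of these had the same direction on all 4 slides with both groups: lymphocyte markers were higher on 3 (-0.43 to 0.63) and epicardial markers on 2 (-0.81 to 2.52). Adipocyte markers were higher on 2 (-1.59 to 6.22), and lower were neutrophil markers and the tricarboxylic acid cycle on 3, glycolysis on 2, and fatty acid oxidation and oxidative phosphorylation on 4. The cardiac stress programme was lower by 0.48 in list mean (1 member lower over the list alone), and its difference ranged from -1.54 to 0.15 over the 4 slides that held both groups. Its adjusted p was 0.000313 by camera, 0.437 with an estimated correlation and 0.262 by exact permutation. Neutrophil markers differed by -0.58, with an adjusted p of 0.00217 by camera, 0.253 with an estimated correlation and 0.212 by exact permutation. Without HF_shDB replicate 6, which stood high in this list, the difference was -0.35 (camera adjusted p = 0.0440). The stress call was lost without the 7 arrays high in atrial markers (adjusted p = 0.760), and the neutrophil call without the 6 arrays high in adipocyte markers (adjusted p = 0.332). Lymphocyte markers differed by 0.44 (3 members higher over the list alone), with an adjusted p of 0.000158 by camera, 0.308 with an estimated correlation and 0.0941 by exact permutation. The energy metabolism lists stood lower in HF_DB, by 0.29 for oxidative phosphorylation, 0.23 for fatty acid uptake and oxidation, 0.17 for the tricarboxylic acid cycle and 0.17 for glucose uptake and glycolysis. Camera called these 4 lists (adjusted p = 4.15e-08, 6.04e-05, 0.000313 and 0.00192, and 0.439, 0.524, 0.524 and 0.574 with an estimated correlation). With quantile normalization none of the 4 was called (adjusted p = 0.418, 0.459, 0.799 and 0.870), and the tricarboxylic acid cycle and glycolysis lists changed sign. All 4 calls were also lost with normexp background correction, with the values of the authors and with the epicardial mean alone as a covariate. Without HF_DB replicate 1 the tricarboxylic acid cycle differed by -0.11 (camera adjusted p = 0.0170). Epicardial and mesothelial markers were higher by 1.23 (6 of 6 over the list alone; adjusted p = 1.64e-06 by camera, 0.253 with an estimated correlation and 0.159 by exact permutation), and adipocyte markers by 1.81 (0 over the list alone; adjusted p = 0.00266, 0.524 and 0.379 in the same order; 1.11 and a camera adjusted p of 0.0441 without HF_shDB replicate 5). The collagen list was not called (difference 0.13, camera adjusted p = 0.192, exact permutation 0.891), but its camera result depended on the setting: higher in HF_DB without the arrays high in atrial markers (7.68e-08), with normexp background correction (0.00652) and without HF_shDB replicate 3 (0.0291) or 5 (0.0488) or HF_DB replicate 2 (0.0162), 3 (0.0306) or 6 (0.000375), and lower with the adipocyte and atrial means as covariates (0.000949). Its sign also turned, without a call, without HF_DB replicate 1 (0.165) and without the arrays high in adipocyte markers (0.792), and it was higher on 2 and lower on 2 of the slides.

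The comparison of HF_DB with sham asks which genes differ from sham 2 weeks after the band was removed. HF_DB mice also had the infarct, and no mice were taken at week 2. A difference from sham thus need not be left over from the constriction. Of the collagens and structural matrix genes 16 of 22 were higher in HF_DB, as were the natriuretic peptide genes and Acta1, and 7 of 25 genes of fatty acid uptake and oxidation and 5 of 24 of oxidative phosphorylation were lower. Timp1 was 4.86-fold higher (log2 difference 2.28 ± 0.42, 6 against 6 arrays), Postn 3.87-fold (1.95 ± 0.46), Acta1 4.40-fold (2.14 ± 0.43), Nppa 2.51-fold (1.33 ± 0.28) and Nppb 2.39-fold (1.26 ± 0.29). Limma called 909 of 18882 genes, 466 higher and 443 lower. Of these, 206 differed by at least 1 log2 unit, 181 higher and 25 lower.

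The largest rises among the genes chosen by rule were in Ecrg4 (3.46 ± 0.84; above background on 2 of 6 sham arrays), the cartilage matrix gene Comp (3.43 ± 0.90), Ltbp2, which encodes a latent growth factor binding protein (3.27 ± 0.87), Dkk3 (3.17 ± 0.88), Ccn5 (2.99 ± 0.66) and the secreted Wnt modulator gene Sfrp2 (2.96 ± 0.74). The largest falls were in Lrrc52 (-1.50 ± 0.40), Vmn1r66 (-1.41 ± 0.38; above background on 2 of 6 HF_DB arrays), Cngb3 (-1.36 ± 0.29), Gpr22 (-1.34 ± 0.29), Ano10 (-1.29 ± 0.29) and the adenylyl cyclase gene Adcy9 (-1.24 ± 0.28). The second probe of Ano10 was higher in HF_DB (0.62, adjusted p = 0.0198), so the array does not give this gene a direction.

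Of the collagens and structural matrix, 16 of 22 genes were higher in HF_DB than in sham (20 over the list alone), among them Col1a1 (1.47 ± 0.40), Col3a1 (1.51 ± 0.38), Mfap4 (1.90 ± 0.40), Bgn (1.18 ± 0.25) and Fbn1 (1.42 ± 0.31). Matrix processing had 10 of 23 higher and 1 lower (14 and 1 over the list alone), including Mmp3 (2.06 ± 0.39), Pcolce (0.67 ± 0.13) and Lox (1.95 ± 0.55), with the inhibitor gene Timp4 lower (-1.18 ± 0.33). Transforming growth factor beta signalling and myofibroblast genes had 9 of 19 higher (13 over the list alone), including the activin subunit gene Inhba (1.60 ± 0.31), Itgbl1 (2.07 ± 0.46) and Tgfb3 (1.13 ± 0.26). The list means were 1.71 ± 0.93 against 0.25 ± 0.49 (SD, n = 6 and 6), 0.94 ± 0.53 against 0.23 ± 0.23 and 0.32 ± 0.59 against -0.88 ± 0.40. Their adjusted exact permutation p was 0.0473, 0.0473 and 0.0315, and camera gave 1.86e-18, 1.51e-08 and 5.66e-12 (adjusted p = 0.253 with an estimated correlation for each). The collagen list mean was higher on each of the 3 slides that held both groups, by 1.14 to 2.08. Matricellular proteins had 5 of 13 higher (8 over the list alone), including Ccn2 (1.62 ± 0.37), with a list difference of 1.30. The adjusted p of this list was 2.71e-08 by camera, 0.253 with an estimated correlation and 0.0649 by exact permutation.

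The cardiac stress programme had 5 of 15 genes higher in HF_DB than in sham (7 over the list alone), including Ankrd1 (1.25 ± 0.26). The list differed by 0.92, with an adjusted p of 3.86e-08 by camera, 0.253 with an estimated correlation and 0.0401 by exact permutation. The difference of Myh7 was 2.05 ± 0.82 (adjusted p = 0.134). Macrophage and monocyte markers differed by 0.33 with 0 of 18 past the threshold (2 over the list alone), with an adjusted p of 8.00e-05 by camera, 0.388 with an estimated correlation and 0.0401 by exact permutation. Fibroblast markers had 3 of 10 higher (7 over the list alone), Pi16 (0.97 ± 0.19), Lum (0.97 ± 0.23) and Dcn (0.42 ± 0.11), with an adjusted p of 2.72e-05 by camera, 0.310 with an estimated correlation and 0.0552 by exact permutation. Lymphocyte markers had 1 of 12 higher (3 over the list alone), the B cell gene Cd79b (1.36 ± 0.39), with an adjusted p of 0.000928 by camera, 0.388 with an estimated correlation and 0.0903 by exact permutation. Egr2 was at least 1.45-fold higher, and the immediate early genes had 1 of 15 past the threshold (1 over the list alone; adjusted p = 0.0387 by camera, 0.584 with an estimated correlation and 0.303 by exact permutation). That camera call was lost without sham replicate 1 (0.212) or 3 (0.0523) or HF_DB replicate 1 (0.216, list difference 0.16 from 0.30), 3 (0.0776) or 6 (0.0638). It was also lost with quantile normalization, the values of the authors or a stricter probe filter, and without the arrays high in adipocyte or atrial markers.

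Fatty acid uptake and oxidation had 7 of 25 genes lower in HF_DB than in sham (21 over the list alone), including Acaa2 (-0.67 ± 0.14), Hadh (-0.64 ± 0.14) and Decr1 (-0.60 ± 0.15). Oxidative phosphorylation had 5 of 24 lower (20 over the list alone), including Cox7b (-0.55 ± 0.13), Ndufs3 (-0.42 ± 0.11) and Cycs (-0.47 ± 0.12). The tricarboxylic acid cycle had 2 of 16 lower (12 over the list alone), Suclg1 (-0.55 ± 0.13) and Fh1 (-0.45 ± 0.11). The list means differed by -0.50, -0.48 and -0.37. Camera gave adjusted p values of 2.10e-10, 7.43e-10 and 6.62e-07 (adjusted p = 0.355, 0.388 and 0.409 with an estimated correlation), and the exact permutation called none of the 3 (adjusted p = 0.0552, 0.0697 and 0.0697). Cpt1b differed by -0.31 ± 0.17 (adjusted p = 0.279). Cardiac ion channels differed by -0.31 with 1 of 16 lower (1 over the list alone), Kcnv2 (-1.07 ± 0.24; adjusted p of the list 0.0225 by camera, 0.524 with an estimated correlation and 0.0764 by exact permutation). Without HF_DB replicate 1, which stood low in this list, the difference was -0.21 and the call was lost (camera adjusted p = 0.142), as it was with both covariates (0.156), the adipocyte (0.0905) or epicardial mean alone (0.0865) and without the arrays high in adipocyte markers (0.263). Among the contractile and calcium handling genes 1 of 20 was lower (2 over the list alone), the calcium binding protein gene Hrc (-0.52 ± 0.14), while Myh6 (-0.19 ± 0.17) and Atp2a2 (-0.27 ± 0.16) did not pass. The adjusted p of that list was 0.00922 by camera, 0.695 with an estimated correlation, 0.215 by exact permutation and 0.418 with quantile normalization. Glucose uptake and glycolysis had 1 of 21 lower (1 over the list alone), Ldhb (-0.53 ± 0.13), with an adjusted p of 0.0408 by camera, 0.747 with an estimated correlation, 0.178 by exact permutation and 0.938, with the opposite sign, with quantile normalization. Its camera call was also lost without sham replicate 3, 4, 5 or 6 or HF_DB replicate 2, 3 or 6 (adjusted p from 0.0528 to 0.109).

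Markers of tissue other than ventricular muscle moved with this comparison. The adipocyte list mean was 2.40 ± 1.66 (SD, n = 6) in HF_DB and -0.89 ± 3.16 (n = 6) in sham, with 0 of 7 members past the threshold (7 higher over the list alone; adjusted p = 0.000266 by camera, 0.447 with an estimated correlation and 0.169 by exact permutation). Epicardial and mesothelial markers were higher by 1.11 (0 over the list alone; adjusted p = 0.00192, 0.474 and 0.215 in the same order) and atrial markers by 1.88 (0 over the list alone; adjusted p = 0.0387, 0.584 and 0.433), whose camera call was lost without sham replicate 2, 5 or 6 or HF_DB replicate 2, 3 or 6 (adjusted p from 0.0538 to 0.125). The epicardial call was lost with both covariates (0.388) and the adipocyte call with the epicardial mean (0.0865). Over the 3 slides with both groups, adipocyte (-2.61 to 6.37), epicardial (-0.73 to 2.16), atrial (-4.22 to 4.76) and lymphocyte markers (-0.29 to 0.78) were higher on 2, contractile genes and glycolysis lower on 2, and immediate early genes higher on 1. Of the 19 camera calls in HF_DB against sham, 14 held without each array in turn and 11 in every other setting run with camera at the preset correlation. With the adipocyte and atrial means as covariates 61 genes passed, with the adipocyte mean alone 26, with slide as a fixed block 146, with normexp background correction 10, and without any 1 array 160 to 2855. The count was 739 without the arrays high in adipocyte markers and 3140 without those high in atrial markers. Of the 47 named genes past the threshold, 8 kept their call without each array in turn (Nppa, Acta1, Timp1, Ankrd1, Mmp3, Pcolce, Inhba and Pi16), 7 kept it with both covariates (Ccn5, Acta1, Timp1, Ankrd1, Mmp3, Itgbl1 and Pi16), 24 without the arrays high in adipocyte markers, 5 with slide as a fixed block, 1 with the adipocyte mean alone and 0 with normexp background correction.

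**Figure D2:**
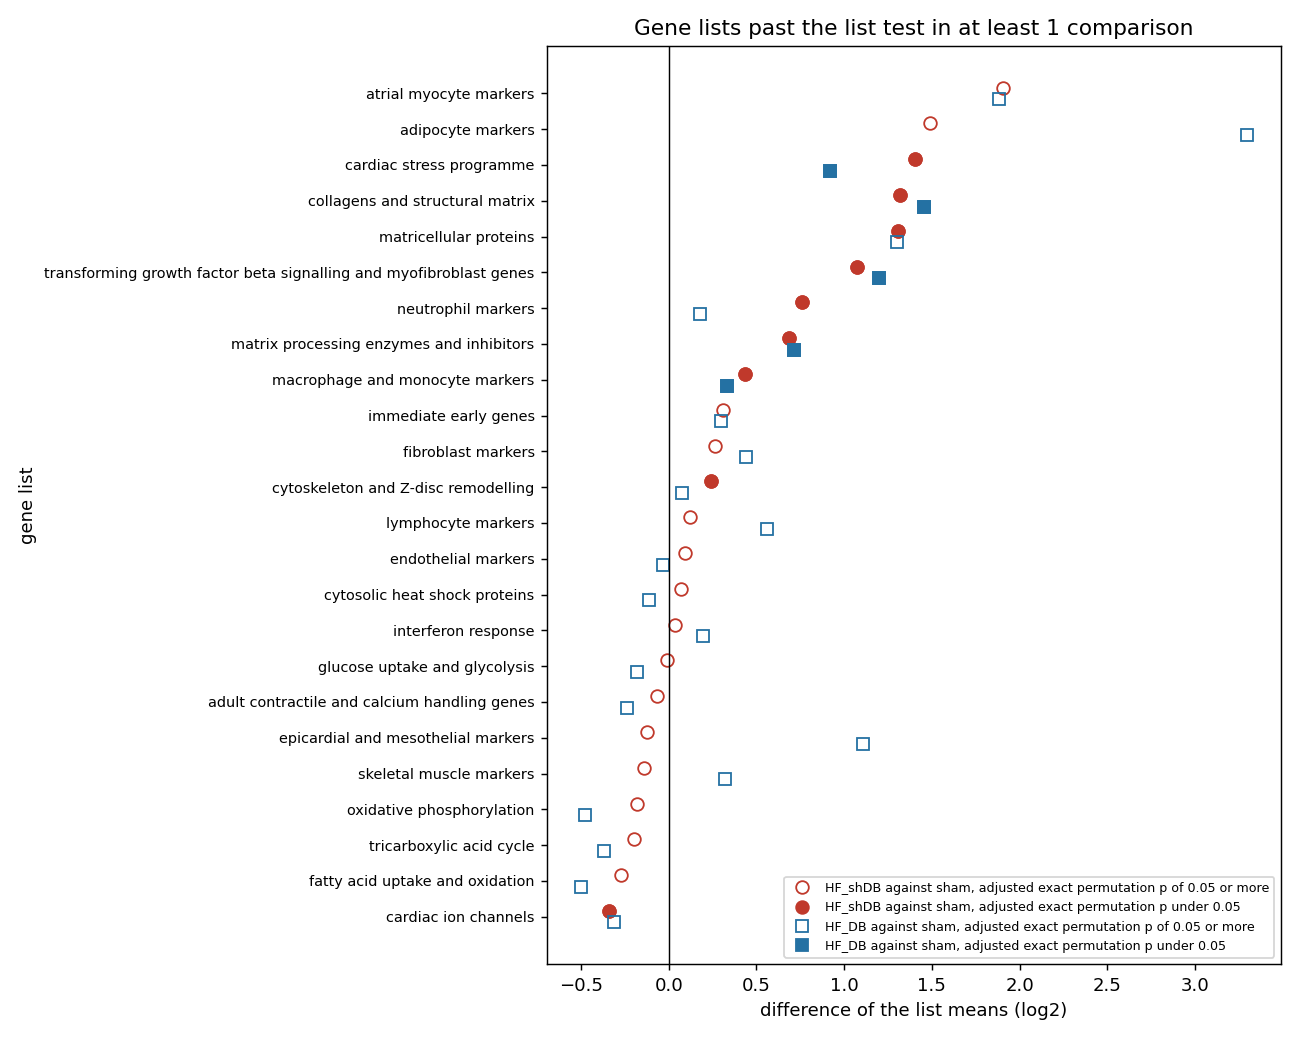
Difference of the list means from sham (log2) for each gene list called by camera in at least 1 comparison, in HF_shDB (red circles) and HF_DB (blue squares). Filled symbols have an adjusted exact permutation p under 0.05, which holds for 9 lists in HF_shDB and 5 in HF_DB.

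Of the 376 genes that differed between HF_shDB and sham, 236 also differed between HF_DB and sham in the same direction (130 higher and 106 lower), and 0 in the opposite direction, where 9.06 in the same direction are expected for independent lists of these sizes. This count was 43 to 534 without any 1 array, 57 with the adipocyte and atrial means as covariates, 24 with the adipocyte mean alone, 128 with slide as a fixed block, 4 with normexp background correction and 248 without the arrays high in adipocyte markers. The 236 genes include Acta1, Nppa, Nppb, Timp1, Postn and Arntl. Both comparisons use the same sham arrays. Groups simulated without any difference gave a median of 0 such genes. Without a difference hardly any gene is called, so that value does not measure what the shared arrays add. When the 6 sham arrays were split so that each comparison had its own controls, a median of 0 genes (0 to 4 over 20 splits) passed in both, with medians of 18.5 and 79.5 genes called in the separate fits. The correlation of the log2 differences across genes, which are not independent replicates, was 0.718 with shared controls, 0.525 in the simulation and 0.522 with split controls. The genes called with HF_DB against sham but not with HF_shDB against sham numbered 673. The difference between the debanded and banded groups itself passed for 0 of them, as for 0 of all 18882 genes.

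None of the 376 genes moved back past the threshold in HF_DB against HF_shDB (limma, 0 genes; 252 had the opposite sign, 119 of the 193 higher and 133 of the 183 lower, 44 of them at an unadjusted p under 0.05). With 0 of 18882 genes called in that comparison, this 0 follows and says nothing particular about the 376 genes. Both comparisons use the HF_shDB arrays, which by itself favours opposite signs. The correlation of their log2 differences was -0.469 in groups simulated without any difference, -0.0387 as observed, and a median of 0.108 (-0.269 to 0.460) over 35 splits in which each comparison had its own HF_shDB arrays. The share of the difference left after debanding was 1.02, the median over 50 splits in which the genes were chosen on one part of the arrays and measured on the other (range 0.781 to 3.17, and under 1 in 20 splits). The median signed difference in the measuring arrays was 0.554 for HF_shDB and 0.600 for HF_DB. Both differences were taken from the same measuring sham arrays. A deviation of those arrays enters both and draws the share toward 1. The share was not run with the marker means as covariates, so unequal tissue can be part of it. It is a median over the chosen genes and does not describe single lists such as the cardiac stress programme. At least 100 genes passed in the choosing arrays in 9 splits, and in the rest the 500 genes with the largest statistic were used. No mice were taken at week 2, so HF_shDB at week 4 stands in for the state before debanding.

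**Figure D3:**
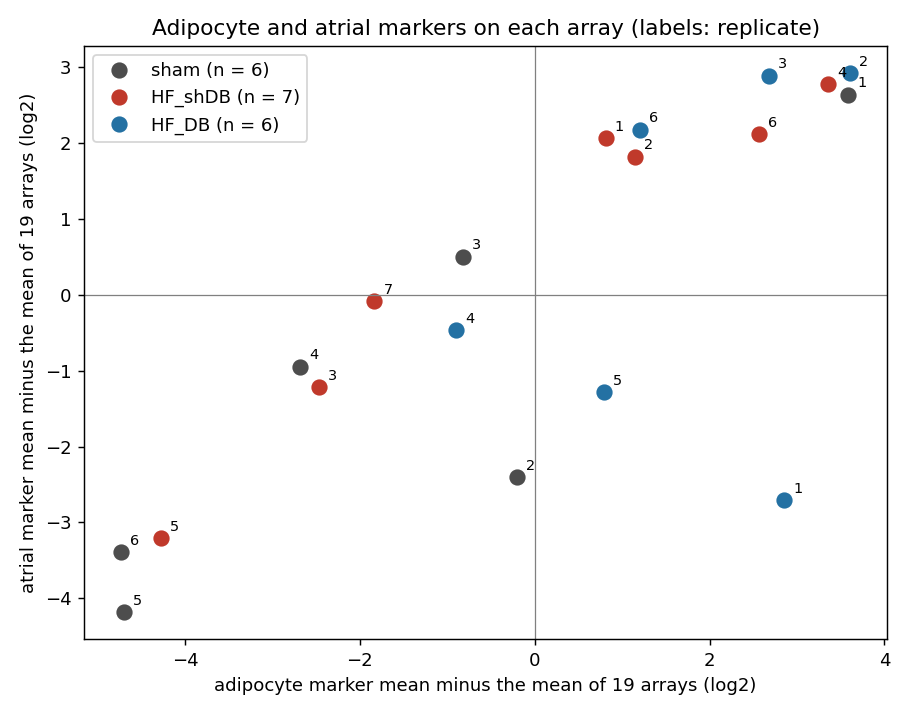
Mean of the adipocyte markers against mean of the atrial myocyte markers on each array (log2, minus the mean of the 19 arrays; numbers are replicates). The arrays spread over both lists in every group, and sham replicate 1 stands with the highest arrays (adipocyte 3.58, atrial 2.64).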

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

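The test of single arrays was planned. Among the tests of explanations below, those of fat and atrial tissue and of slide for the count of genes, of infarct and border tissue, of the time of day, and of all the called clock genes were chosen after results they bear on had been seen.

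A test of single arrays marked 13 of the 233 groups of values tested as having an array far from the others, where chance marks about 1 in 20 groups (11.65 expected). Among genes, Ccn2 stood at 5.99 in HF_shDB replicate 1 (3.97 to 4.82 in the others) and Dcn at 7.18 in HF_DB replicate 1 (6.64 to 6.81). In sham, Decr1 stood low at 4.98 in replicate 1 (5.48 to 5.78), Cd79b high at -0.34 in replicate 1 (-3.37 to -2.85) and Itgbl1 high at -1.09 in replicate 2 (-2.64 to -2.35). Among list means, given relative to the mean of all arrays, HF_DB replicate 1 stood low in cardiac ion channels (-0.61) and high in skeletal muscle markers (1.74). HF_shDB replicate 1 stood low in the interferon response (-0.98) and high in cytoskeleton and Z-disc remodelling (0.57). HF_shDB replicate 6 stood high in neutrophil markers (1.80) and lymphocyte markers (0.61), HF_DB replicate 6 in neutrophil markers (0.53), and HF_shDB replicate 4 in fibroblast markers (0.68).

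More genes differed from sham in HF_DB (909) than in HF_shDB (376). This order rests on single arrays and settings: HF_DB had fewer genes without HF_DB replicate 1 (238 and 531) or 4 (382 and 385) or sham replicate 6 (247 and 260), with normexp background correction (10 and 33), with the epicardial mean as a covariate (52 and 752) and at an adjusted p under 0.01 (28 and 70). Brighter HF_DB arrays met the rule set beforehand for rejecting them as an explanation. Their log2 75th percentile differed from sham by 0.474 sham SDs (at most 0.804 without any 1 array; exact permutation p = 0.400). With 6 against 6 arrays that test cannot exclude a difference. The mean 75th percentile was 2017 in HF_DB (SD 426) and 1815 in sham (SD 422). No fit took brightness as a covariate, so this explanation stays open. Unequal fat and atrial tissue cannot be told apart from an effect of debanding: with both marker means as covariates the median signed difference of the 909 genes went from 0.67 (median SE 0.159) to 0.55 (SE 0.166), a ratio of 0.818 (0.746 to 0.888 without any 1 array, on both sides of the bound of 0.8 set to exclude it), 909 kept their sign, and the counts became 61 for HF_DB and 766 for HF_shDB. Differences became smaller and standard errors larger, and the median adjusted p of the 909 genes went from 0.0312 to 0.150. With the adipocyte mean alone the ratio was 0.849 (SE 0.171) and the counts 26 and 411. The order held with the atrial mean alone (519 and 507), without the arrays high in adipocyte markers (739 and 451) and without those high in atrial markers (3140 and 273). Leaving arrays out did not make the amounts of fat equal. In both fits the sham arrays kept had adipocyte means of -4.74 to -0.20, relative to the mean of all arrays. The HF_DB arrays kept had -0.90 to 1.20 without the arrays high in adipocyte markers and -0.90 to 2.85 without those high in atrial markers. The fits without arrays thus do not bear on unequal fat. For slide the ratio was 0.913 (0.838 to 0.964), above the same bound throughout, but that bound was judged wrong after the value was seen, because the counts still turned over to 146 and 598. The standard error hardly moved there (0.1587 to 0.1598) while the median adjusted p of the 909 genes went to 0.0837, and why so many calls ended was not tested. A biological difference between debanded and banded hearts passed limma for 0 genes (1389 at an unadjusted p under 0.05) and stays open.

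Stress genes varied widely among the HF_DB arrays, over a range of 1.38 in the mean of the stress list. Dilution of ventricular myocytes stays open, since the contractile list ranged over 0.53, a ratio of 0.381 (0.348 to 0.429 without any 1 array) that lies between the bounds set. Sections that hold different amounts of infarct and border tissue stay open too, because stress and collagen list means rose and fell together within groups over the 13 arrays with constriction and infarction (r = 0.776, permutation p = 0.00185; rho = 0.819, permutation p = 0.00106; r = 0.816 without the 2 arrays farthest from the median). That relation was r = 0.549 within HF_shDB and 0.907 within HF_DB, and hearts that differ in disease severity would give it as well. The labels give no infarct size or cardiac function per mouse, so recovery that differs between mice was not tested.

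Clock genes moved in opposite directions in HF_shDB. A score, the mean of 3 activator genes minus that of 5 genes of the opposing arm, was -4.75 ± 0.31 in sham (SD, n = 6), -3.03 ± 0.56 in HF_shDB (n = 7) and -3.35 ± 0.53 in HF_DB (n = 6). Fat and atrial tissue and slide are argued against, since the difference from sham of HF_shDB was 1.05 times its size with the covariates (1.02 to 1.11 without any 1 array) and 0.966 times with slide as a block (0.927 to 1.01). The score leaves out Nr1d1 and Cry2, which were called. Over all 6 called clock genes the median signed difference was 0.982 (0.946 to 1.06) and 0.951 times (0.853 to 1.01) its size in the same order, and 6 and 6 kept their call. The time of day at harvest was not tested and cannot be told apart from an effect of disease, because the labels give no harvest time. The separation of HF_shDB from sham by the score (exact permutation p = 0.00117) does not bear on it, since the genes were chosen for this pattern. The clock genes outside the score did not all move 1 way. Nr1d1 (0.80), Bhlhe40 (0.27) and Bhlhe41 (0.29) were higher in HF_shDB, and Nr1d2 (-0.58), Cry2 (-0.68) and Ciart (-1.11) were lower. Among these, Nr1d1 and Cry2 passed the threshold. The score did not separate HF_DB from HF_shDB (exact permutation p = 0.312), which does not show that they are equal.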

How the results depend on the processing

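Slide as a fixed block, the marker covariates, the fits without arrays high in adipocyte or atrial markers and the exact permutation of list means were chosen after the data had been seen, and the other alternatives were planned. The 3 counts below are HF_shDB against sham (376), HF_DB against sham (909) and genes still different after debanding (236). All stayed within a factor of 1.5 with quantile normalization, the values of the authors, the stricter filter, the mean over probes, fits of the compared groups alone, trend and robust moderation, and without the arrays high in adipocyte markers. HF_DB against HF_shDB stayed at 0 genes in all of these and in the settings below, with 1 exception. Genes moved back therefore had to stay at 0, and were 0 in the exception as well. Beyond the factor of 1.5, the counts were 33, 10 and 4 with normexp, where the median standard error of HF_shDB against sham was larger (0.182 against 0.141) and the median difference of the called genes smaller (0.807 and 0.809 times for the first 2), 241, 402 and 136 without a filter, where more genes were tested, and 2843, 6541 and 2139 with array weights. Those weights were 6.67 for sham replicate 4 and 0.37 to 1.87 for the other arrays. The weighted comparisons with sham thus lean on 1 array. The counts were 70, 28 and 17 at an adjusted p under 0.01 and 101, 206 and 59 with a difference of at least 1 log2 unit, which follows from the stricter rule. Slide gave 598, 146 and 128 as a fixed block, and 709 and 400 for the first and last as a random block. With both covariates they were 766, 61 and 57, with the epicardial mean alone 752, 52 and 46, with the adipocyte mean alone 26 and 24 for the last 2, and with the atrial mean alone 519 for HF_DB against sham. Without the arrays high in atrial markers HF_DB against HF_shDB gave 6 genes (the exception), HF_DB against sham 3140, and the share of the difference left became 1.52 from 1.02. Except for the filter and the stricter rules, the cause was not tested. A planned block on replicate numbers gave 161, 296 and 107, but the numbers do not pair the arrays. Same-number pairs had a median r of -0.118 over 18 pairs, and 1 of 19 arrays correlated best with its own number. This block thus removes degrees of freedom, and takes HF_shDB replicate 7, alone with its number, out of the comparisons. Scan date was not run, since there was 1 scan day.

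Without each array in turn, HF_shDB against sham ranged from 88 to 635, HF_DB against sham from 160 to 2855, still different from 43 to 534, the share left from 0.908 to 1.16 and the lists called from 46 to 53, while HF_DB against HF_shDB and moved back stayed at 0. The first count moved by over 1.5 times without sham replicates 1 (635), 3 (247), 4 (104) and 5 (88) and HF_shDB replicates 5 (229) and 6 (180). The second did so without sham replicates 1 (2855), 2 (450), 4 (203), 5 (160) and 6 (247) and HF_DB replicates 1 (238), 2 (473), 3 (524) and 4 (382). The third did so without sham replicates 1 (534), 4 (54), 5 (43) and 6 (113), HF_shDB replicates 5 (146) and 6 (131) and HF_DB replicates 1 (148) and 4 (150). Of 81 calls of named genes 26, and of 51 calls of lists 37, held without each array.

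The lists called (51) became 0 with an estimated correlation, 16 with fry and 14 with the exact permutation, and were 37 to 56 in the other settings. In HF_DB against HF_shDB these lists, called in at least 1 of the fits compared, took the opposite sign. Lists called in neither fit also did, for example 11 of 102 tests with quantile normalization and 15 without the arrays high in adipocyte markers. With quantile normalization they were the tricarboxylic acid cycle (adjusted p = 0.799) and glucose uptake and glycolysis (0.870, and 0.938 against sham), and with the values of the authors the same lists (0.840 and 0.975). With both covariates they were collagens and structural matrix (0.000949, now lower), matricellular proteins (0.00454), matrix processing enzymes (0.00335), transforming growth factor beta signalling (0.0113) and fibroblast markers (0.737). With the adipocyte mean alone they were atrial markers (0.0263, and 0.796 against sham), and with the epicardial mean alone contractile genes (0.630), glycolysis (0.726), transforming growth factor beta signalling (0.0409), atrial markers (0.000253) and adipocyte markers (0.157). Without the arrays high in adipocyte markers they were red blood cell markers (0.0149) and the mitotic cell cycle (0.00788), and without HF_DB replicate 1 matricellular proteins (0.0467, within 0.0467 to 0.965 over the arrays left out). In HF_shDB against sham adipocyte markers did so with the atrial mean alone (0.982). The other probe of Ano10 had the opposite sign in both comparisons with sham (0.37 and 0.62). The causes were not tested. No other call of a named gene changed sign, and the arrays had 56.2% to 65.1% of spots well above background, so genes nearer the background are less certain.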

Other observations

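The splits below were planned. The levels of single markers and the marker lists used as covariates were chosen after the arrays had been seen to differ in them.

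Several lists in HF_DB against HF_shDB were called by camera and by no exact permutation, and no member of them passed the threshold. Skeletal muscle markers (list difference 0.46), the interferon response (0.16) and fibroblast markers (0.18) were higher in HF_DB, with adjusted p values of 0.00652, 0.00806 and 0.0134 by camera (0.388, 0.695 and 0.524 with an estimated correlation). Lower were adult contractile and calcium handling genes (-0.17), cytoskeleton and Z-disc remodelling (-0.17), endothelial markers (-0.13) and cytosolic heat shock proteins (-0.18), with adjusted p values of 0.00329, 0.00345, 0.0209 and 0.0346 (0.655, 0.425, 0.253 and 0.524 with an estimated correlation). With quantile normalization, these 4 were not called (adjusted p = 0.740, 0.195, 0.403 and 0.504). The skeletal muscle call was lost without HF_DB replicate 1, the array that stood high in this list (0.17, adjusted p = 0.142). The interferon call was lost without HF_shDB replicate 1, which stood low in it (difference under 0.01, adjusted p = 0.763), or HF_DB replicate 2 (0.0597) or 4 (0.107, difference 0.10). The fibroblast call was lost without HF_shDB replicate 1 (0.0812) or HF_DB replicate 1 (0.235, difference 0.09), and its difference was 0.29 without HF_shDB replicate 4 (5.39e-05). Without HF_shDB replicate 1 the contractile call was lost (0.0616, difference -0.11), and the cytoskeleton list, in which that array stood high, differed by -0.09 (0.0492). The endothelial call was lost without HF_shDB replicate 2 (0.0736) or HF_DB replicate 6 (0.120), and the heat shock call without HF_shDB replicate 2 (0.171) or 3 (0.149) or HF_DB replicate 5 (0.111) or 6 (0.120). Over the 4 slides with both groups the direction held on 4 for skeletal muscle and endothelial markers, on 3 for interferon, fibroblast, cytoskeleton and heat shock genes and on 2 for contractile genes. The interferon response was also called in HF_DB against sham (difference 0.19, adjusted p = 0.0142 by camera, 0.724 with an estimated correlation and 0.475 by exact permutation), a call lost without sham replicate 5 (0.158, difference 0.09) or HF_DB replicate 2 (0.0636) or 4 (0.0552).

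Other lists were called by camera in no comparison. In HF_shDB against sham the list means differed by 0.02 for adrenergic, natriuretic and angiotensin signalling, -0.05 for smooth muscle and pericyte markers, -0.07 for nerve and Schwann cell markers, -0.04 for red blood cell markers, 0.21 for cytokines and chemokines, 0.09 for endoplasmic reticulum stress and secretory chaperones, -0.03 for atrophy, ubiquitin ligase and autophagy genes, 0.06 for the mitotic cell cycle and 0.10 for reference genes. Their adjusted camera p values were 0.645, 0.645, 0.490, 0.969, 0.258, 0.0979, 0.920, 0.490 and 0.0851. Single members did pass, and they are named here after their values were seen. The chemokine gene Ccl8 was higher in HF_shDB (1.85 ± 0.40) and in HF_DB (1.75 ± 0.42) than in sham, and the adenylyl cyclase gene Adcy6 was lower in both (-0.61 ± 0.12 and -0.54 ± 0.12). In HF_DB the pericyte genes Rgs5 (-0.71 ± 0.18) and Abcc9 (-0.60 ± 0.17), the myelin gene Plp1 (-0.82 ± 0.22) and the chaperone gene Canx (-0.36 ± 0.09) were lower than in sham, and Pdia4 (0.71 ± 0.17) and the reference gene Gusb (0.35 ± 0.10) were higher. Of the endothelial list, called in HF_DB against HF_shDB alone, Flt1 was lower in HF_DB than in sham (-0.54 ± 0.12). Clock genes past the threshold in HF_DB against sham were Arntl (1.57 ± 0.28), Nr1d1 (0.69 ± 0.16), Tef (-0.69 ± 0.14) and Hlf (-0.87 ± 0.16).

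The adipocyte markers Cfd and Car3, the 2 that lay well above background on every sham array, stood at 1.46 ± 3.59 and 1.05 ± 3.55 in sham (SD, n = 6), 3.38 ± 3.05 and 2.59 ± 3.00 in HF_shDB (n = 7) and 5.27 ± 1.37 and 4.62 ± 1.47 in HF_DB (n = 6). The atrial markers Myl4 and Myl7 stood at 3.78 ± 2.48 and 1.95 ± 3.38, 5.77 ± 2.21 and 4.44 ± 2.74, and 5.60 ± 2.10 and 4.25 ± 3.03 in the same order. None of the 7 adipocyte, 5 atrial and 6 epicardial markers measured is in another list (0 of each), and 2, 4 and 4 of them lay well above background on every sham array. The adipocyte list mean ranged over the arrays from -4.04 to 4.31 and the atrial one from -2.26 to 4.84. The main axis of variation within groups held 32.9% of the variance, and sham replicate 1, HF_shDB replicates 4 and 6 and HF_DB replicates 2 and 3, high in both lists, stood highest on it. No sort or gate removes such tissue from a section.

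The arrays were put into groups of the same sizes in 100 splits, the real split included. For the genes called in HF_shDB against sham, 1 split gave 376 or more, the real one, and the highest other gave 37. This argues against chance as far as 100 splits can. The splits were run with the main processing alone. They were not repeated with normexp background correction, under which the real count was 33. For the genes that still differed after debanding, 1 split gave 236 or more and the highest other gave 2. These splits shuffle all groups at once, so they argue only against the case that no group differs. They do not tell the overlap apart from an effect of the shared sham arrays. For HF_DB against sham 3 splits gave 909 or more, under the bound set (under 5 of 100). The highest other gave 3286, so this is weak evidence against chance. A count several times the real one points to a structure of the samples, but this split kept 10 of the 12 real labels, so the real difference between the groups can be part of its count, and what else it follows was not resolved: its difference in the adipocyte list mean (4.09, where the real groups differ by 3.30) ranked 3 among the splits. For HF_DB against HF_shDB (0 genes, highest other 59) and for genes moved back (0, highest other 0), all 100 splits had to give as many. The test therefore decides nothing about chance there. The number of lists called by camera was 51, and 4 splits gave as many, with the highest other at 51 as well. The other splits called a median of 30 lists, and 99 of them at least 1, so many camera calls arise without the real groups. The 4 splits lie under the bound set (under 5 of 100), but other splits reached the same number, so chance is not excluded for this count.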
